A study of Arabidopsis thaliana with 8 samples.

How the data were processed

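Transcript levels were measured in shoots of untreated Arabidopsis thaliana plants, accession Columbia, 18 days old, grown in a greenhouse at 20 °C and 35% humidity with 18 h of light. Each replicate was a pool of 6 plants, per the series' design text, and total RNA was amplified into biotin-labelled cRNA before hybridisation, per the labels' protocols. The 8 arrays held 1 colour each and fell into 4 genotypes with 2 biological replicates per genotype: wild type, lhp1-4, bpc4 bpc6 and lhp1-4 bpc4 bpc6. Each array was assigned to its genotype and replicate number from its label alone. Scanner files were not used here.

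The deposited table holds 1 intensity per probe set and array. Per the submitters' processing notes the authors used RMA, which corrects the background, quantile-normalises the arrays and summarises the probes of a probe set. Its version and the probe set definition are not given in the sources used here. RMA usually writes log2 values. The deposited values were linear, ranged from 1 to 999.7, and no value reached 1000. From these values it was inferred that intensities of 1000 or more were stored divided by 1000. The labels do not state this, and it was not checked against scanner files. As deposited, 809 of 22746 probe sets differed by over 100-fold between some arrays, and 636 replicate pairs differed by over 100-fold.

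This scale was restored before any test. A value under 3, or a value of 10 to 100 written with 3 decimals, was multiplied by 1000, as was a value of 10 to 100 with fewer decimals that then lay within 5-fold of such a value of the same probe set. Values of 3 to 10 could be either a dim signal or a divided value. Such a value was settled where it lay within 5-fold of an already settled value of the same probe set under the first reading and at least 20-fold away under the other. Where all 8 values of a probe set lay between 3 and 10, they were assumed to share 1 reading, and mixed readings would go unseen. Fold changes then do not depend on the reading, so the probe set was tested as it stood and its level was left open. That applied to 5007 probe sets, 22.0% of all. Values were scaled in 1763 probe sets, 7.75%. A further 30 probe sets, 0.132%, could not be settled and were left out, together with 1 control probe set, which left 22716 probe sets. After restoration 1 probe set differed by over 100-fold between arrays and 0 replicate pairs did. The correlation of log2 intensities between replicates went from 0.935 to 0.993 in wild type, from 0.957 to 0.997 in lhp1-4, from 0.941 to 0.995 in bpc4 bpc6 and from 0.938 to 0.994 in lhp1-4 bpc4 bpc6. Part of that gain is built in, because some values were settled by their closeness to others of the same probe set. In the 15289 probe sets whose values were all read on their own, without reference to other values, the correlation went from 0.881 to 0.986 in wild type, from 0.921 to 0.995 in lhp1-4, from 0.892 to 0.990 in bpc4 bpc6 and from 0.884 to 0.988 in lhp1-4 bpc4 bpc6. Among these, the wild type replicates of 171 probe sets had 1 of their 2 values scaled, and their median difference went from 853-fold to 1.17-fold. The rule was tested on simulated data made from the restored values of the 17709 probe sets that it had settled. Each probe set was multiplied by a random factor, its values were kept above 3, and they were shrunk again in the same way. The rule then left 15 probe sets undecided and returned a wrong fold between arrays for 0. Folds in the simulated data were those the rule itself had returned, with at most 1 probe set over 100-fold. A wrong fold would mostly need a dim value of 3 to 10 beside values of 1000 or more. Such cases were nearly absent, so 0 wrong folds could be foreseen and do not show that such values are read rightly. No simulated dim value could lie under 3, so the misreading of such a value was not tested. That simulation assumes the same way of shrinking, so it tests the rule and not the assumption.

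Each comparison used log2 of the restored intensities in limma 3.58.1 under R 4.3.3, with 1 group-means model over all 8 arrays and the default empirical Bayes moderation. The test had been planned for log2 values as deposited, with log2 taken first if the values were linear. The model had 4 residual degrees of freedom and gained 2.85 from moderation. The 6 contrasts were each mutant genotype against wild type, lhp1-4 bpc4 bpc6 against each of its parts, and the interaction, which is the lhp1-4 bpc4 bpc6 value plus the wild type value minus both the lhp1-4 and the bpc4 bpc6 values on the log2 scale. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Fold changes are on the log2 scale with no pseudocount, and errors are the moderated standard errors. Dim probe sets were kept, and log2 changes of dim probe sets understate changes in transcript. The number of arrays limits the precision: the median standard error of a log2 change between genotypes was 0.13, and that of an interaction 0.18.

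The fit was tested on simulated data for the comparison of lhp1-4 with wild type over 22716 probe sets, of which 200 were changed. It recovered 28.4% of those changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 11 false calls. Correlations of log2 changes are across probe sets, which are not independent replicates. Where comparisons shared the wild type arrays, 50 simulations of unchanged genotypes gave the correlation and covariance that sharing alone produces under 2 conditions. Every genotype has the same spread, and noise is independent between probe sets and arrays. Covariances were also taken between differences of single arrays that shared no array.

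The probe sets to be named were to be those with the largest rises and falls among called probe sets whose mutant arrays both lay beyond both reference arrays. The rule asked for 10 rises and 10 falls in each comparison with wild type, 5 and 5 in each other contrast, and further genes among those shared by lhp1-4 and bpc4 bpc6. It also asked for probe sets paired with exactly 1 gene. The sources used here do not pair probe sets with genes, so that part could not be applied, and the first 2 rises and the first 2 falls are given by identifier for each contrast. For the same reason the transcripts of LHP1, BPC4 and BPC6 and the 23 gene lists fixed beforehand were not analysed here.

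The alternatives fixed before the data were examined were a block for the replicate number, only the genotypes compared in the model, leaving out the 30% dimmest probe sets, centring each array on its median, quantile normalization between arrays, trended and robust moderation, array weights, a 2-fold minimum, an adjusted p under 0.01 and leaving out each of the 8 arrays in turn. Chosen after seeing the data were the values as deposited, only probe sets without scaled or open values, floors of 2.5 and 3.5 in place of 3, and reading the undecided probe sets as dim. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.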

Results

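Array measurements were taken from shoots of 18-day-old plants of 4 genotypes: wild type, lhp1-4, bpc4 bpc6 and lhp1-4 bpc4 bpc6, the last referred to as the triple mutant. LHP1 (LIKE HETEROCHROMATIN PROTEIN 1) is a chromodomain protein that acts with the Polycomb group in transcriptional silencing. BPC4 and BPC6 are BASIC PENTACYSTEINE proteins, which bind GAGA motifs in DNA. The title of the series places LHP1 at GAGA motifs through BPC6, and the genotypes allow the effect of each lesion to be measured with and without the other. There were 2 arrays per genotype, each from a pool of 6 plants. Probe sets are given by their array identifiers, because the sources used here do not pair them with genes. The transcripts of the mutated genes were not analysed here, so the genotype labels were not checked against them.

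Median intensities of the 8 arrays ran from 54.7 to 58.3. Replicates of a genotype correlated at 0.993 to 0.997 across 22716 probe sets, and the median absolute log2 difference between replicates was 0.10 in lhp1-4, 0.11 in bpc4 bpc6, 0.14 in the triple mutant and 0.15 in wild type. Arrays of different genotypes correlated nearly as highly, at up to 0.992, between bpc4 bpc6 replicate 2 and wild type replicate 2. The first principal component held 60.5% of the variance and ordered the genotypes. Both wild type arrays and both bpc4 bpc6 arrays lay on its positive side, with scores from 27.7 to 36.1. The lhp1-4 arrays scored -13.9 and -18.5, and the triple mutant arrays -50.3 and -51.3. The second component, with 12.8%, separated wild type, at 16.9 and 28.0, from bpc4 bpc6, at -22.8 and -23.6.

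**Figure D1:**
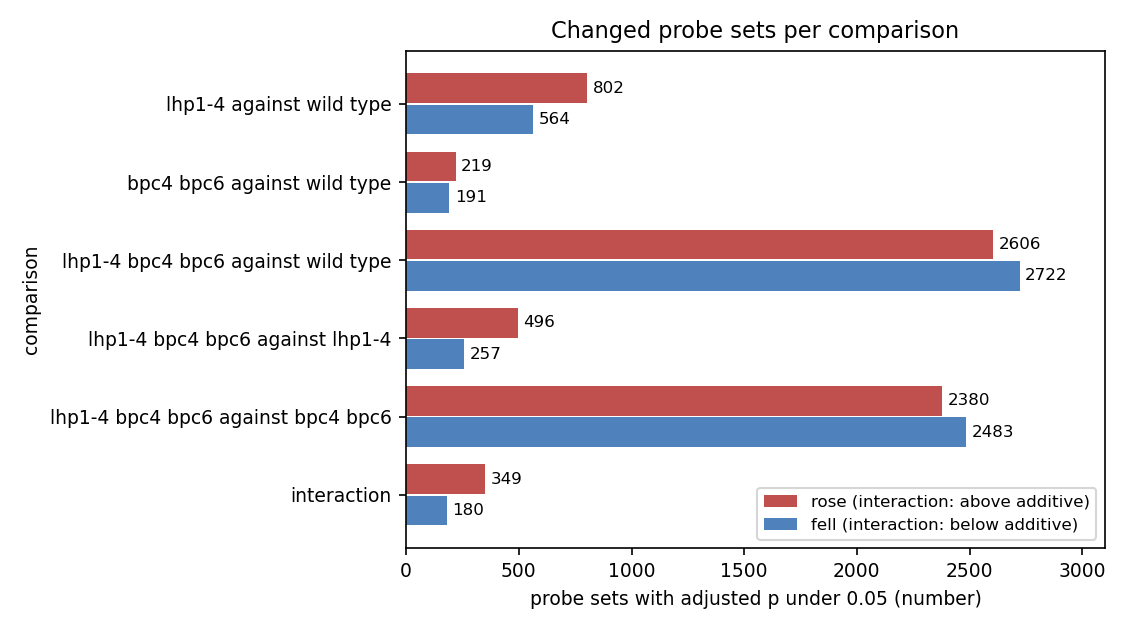
Number of probe sets that rose or fell at a Benjamini-Hochberg adjusted p under 0.05 (limma) in each comparison, with 2 arrays per genotype; for the interaction the bars count probe sets above or below the sum of the separate lhp1-4 and bpc4 bpc6 changes. The comparisons of the triple mutant with wild type (2606 rose, 2722 fell) and with bpc4 bpc6 (2380 rose, 2483 fell) held the most calls.

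The effect of losing LHP1 was measured by comparing lhp1-4 with wild type. In lhp1-4 802 probe sets rose and 564 fell, with a median log2 change of 0.95 among the rises and -0.74 among the falls. Changes of at least 2-fold were mostly upward, with 361 rises and 162 falls. Probe sets that rose were dimmer in wild type than those that fell, with median intensities of 70.0 and 228. The median was 105 over the 17709 probe sets whose level was settled. Over all probe sets tested, with those of open level taken as they stood, the wild type arrays had medians of 54.7 and 54.8. The largest rise was in 246687_AT, from an intensity of 13.8 in wild type to 732 in lhp1-4, a log2 change of 5.73 ± 0.27 (SE, n = 2 arrays per genotype; limma adjusted p = 0.000254). Probe set 245275_AT followed, with intensities of 16.4 and 685 and a log2 change of 5.38 ± 0.46 (limma adjusted p = 0.00205). Probe set 247878_AT fell from 136 to 7.68, a log2 change of -4.15 ± 0.17 (limma adjusted p = 0.000254), and 258419_AT fell from 2012 to 114, a log2 change of -4.14 ± 0.42 (limma adjusted p = 0.00358). For all 4 probe sets both lhp1-4 arrays lay beyond both wild type arrays, as the rule for naming required and as held for all 1366 calls. The direction of 258419_AT rests on the restored scale, since the values as deposited gave 5.82. The number of calls fell when either lhp1-4 array or wild type replicate 1 was left out, which also lowers the degrees of freedom. Rises made up 58.7% of calls but 44.7% once each array was centred on its median, with 727 rises and 898 falls. Rises were also fewer than falls without wild type replicate 2, at 831 and 1001 of 1832 calls.

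Losing BPC4 and BPC6 together changed fewer probe sets than losing LHP1. In bpc4 bpc6 219 probe sets rose and 191 fell against wild type, of which 89 and 56 changed at least 2-fold. Median log2 changes were 0.94 among the rises and -0.82 among the falls. Probe set 260522_X_AT rose from 33.6 to 353, a log2 change of 3.39 ± 0.28 (SE, n = 2 arrays per genotype; limma adjusted p = 0.00733), and 263402_AT rose from 13.6 to 85.9, a log2 change of 2.66 ± 0.17 (limma adjusted p = 0.00361). The largest fall was in 247878_AT, which also led the falls in lhp1-4, from 136 to 17.3, a log2 change of -2.98 ± 0.17 (limma adjusted p = 0.00361). Probe set 262931_AT fell from 329 to 51.1, a log2 change of -2.69 ± 0.17 (limma adjusted p = 0.00361). With each array centred on its median the balance turned, to 263 rises and 322 falls, or from 53.4% to 45.0% rises. The count of 410 calls rested on the pooled spread: with wild type and bpc4 bpc6 alone in the model limma called 0 at adjusted p under 0.05 and 3139 at unadjusted p under 0.05, the smallest adjusted p being 0.0557, and array weights gave 161. It fell to 41 without wild type replicate 1, 82 and 61 without bpc4 bpc6 replicates 1 and 2, 64 without either lhp1-4 array and 192 without either triple mutant array.

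**Figure D2:**
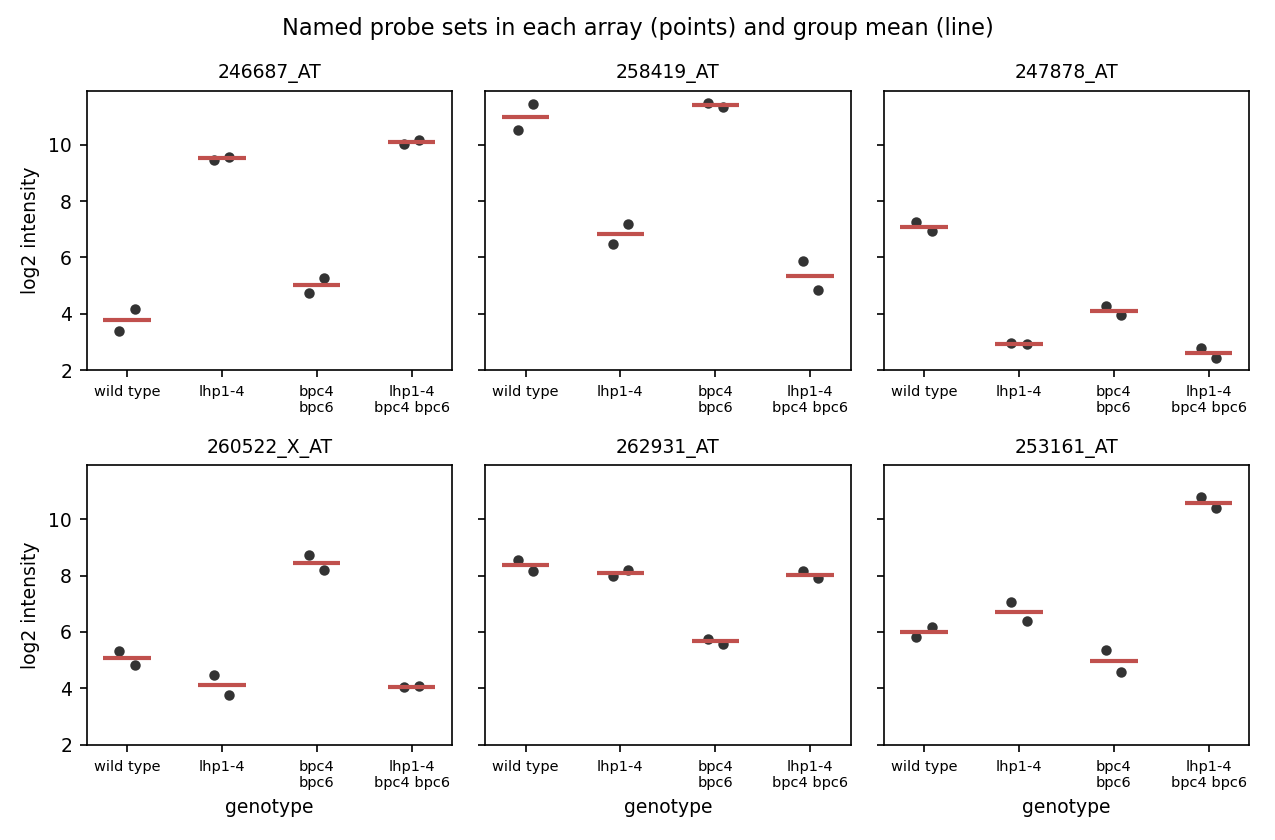
Log2 intensity of 6 named probe sets in each array (points, 2 per genotype) with the genotype mean (line). Probe set 246687_AT was high in lhp1-4 and the triple mutant, 258419_AT was low in both, 247878_AT was low in all mutants, 260522_X_AT and 262931_AT stood apart in bpc4 bpc6 alone, and 253161_AT was high in the triple mutant, at a mean intensity of 1546.

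Whether both lesions act on the same transcripts was addressed through the calls shared by lhp1-4 and bpc4 bpc6. Both mutants raised 92 probe sets and lowered 64, and 10 moved in opposite directions. Independent lists of these lengths would share 7.73 rises and 4.74 falls. Among the 219 rises of bpc4 bpc6 the median log2 change in lhp1-4 was 0.48, and among its 191 falls it was -0.34. Across probe sets the changes correlated with Pearson's r = 0.442 and Spearman's rho = 0.457, but both comparisons used the same wild type arrays, and simulated unchanged genotypes gave r = 0.50 on average, from 0.471 to 0.526. The covariance was 0.0563 against a simulated 0.0133, a difference of 0.0431. The simulation gave every genotype the same spread, but wild type replicates differed most, by a median of 0.15 on the log2 scale. The simulated covariance can thus be too low and the difference too large. Noise in the simulation was also independent between probe sets and arrays, so its range of r can be too narrow. With lhp1-4 and bpc4 bpc6 measured against different wild type arrays, the covariance of single arrays was 0.0217 to 0.0447 over 8 pairings. The 156 shared calls dropped to 22 and 24 without lhp1-4 replicates 1 and 2, 23 without wild type replicate 1, 30 and 32 without bpc4 bpc6 replicates 1 and 2 and 83 without either triple mutant array, and rose to 254 without wild type replicate 2. With only the genotypes compared in each model 0 were shared, since bpc4 bpc6 then had 0 limma calls at adjusted p under 0.05 and 3139 at unadjusted p under 0.05, array weights gave 78, and part of the excess over independent lists can come from the shared wild type arrays.

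The triple mutant differed from wild type in far more probe sets than either parent genotype did. It had 2606 rises and 2722 falls, 23.5% of all probe sets tested, of which 1006 and 443 were at least 2-fold. It kept most of the lhp1-4 changes: of the 802 rises of lhp1-4, 735 also rose in the triple mutant, and of the 564 falls 519 also fell. Of the bpc4 bpc6 changes it shared 120 of 219 rises and 96 of 191 falls, while 20 of those rises fell and 30 of those falls rose. Independent lists would share 92.0 rises and 67.6 falls with lhp1-4, and 25.1 rises and 22.9 falls with bpc4 bpc6. These comparisons share the wild type arrays, which by itself favours overlap. Probe set 246687_AT reached 1087, a log2 change of 6.30 ± 0.27 (SE, n = 2 arrays per genotype; limma adjusted p = 6.76e-05), and 245275_AT reached 705, a log2 change of 5.42 ± 0.46 (limma adjusted p = 0.000586). Probe set 258419_AT fell to 40.9, a log2 change of -5.62 ± 0.42 (limma adjusted p = 0.000375), and 255298_AT fell from 641 to 18.4, a log2 change of -5.12 ± 0.15 (limma adjusted p = 2.59e-05). Directions of 246687_AT and 258419_AT rest on the restored scale, as the values as deposited gave -3.66 and 4.35. With only these 2 genotypes in the model 3369 probe sets were called.

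The lhp1-4 effect was next measured where BPC4 and BPC6 were already lost. Against bpc4 bpc6 the triple mutant had 2380 rises and 2483 falls. Of the 802 rises of lhp1-4 over wild type 599 rose here too and 16 fell, where independent lists would share 84.0, and of its 564 falls 378 fell and 12 rose, where 61.6 would be shared. No array is common to these comparisons. The median log2 change of the 802 rises was 0.95 with BPC4 and BPC6 present and 0.96 without, and that of the 564 falls was -0.74 and -0.70. Probe sets chosen the other way round gave unequal medians: the 2380 rises over bpc4 bpc6 had a median log2 change of 0.82 there and 0.33 in lhp1-4 against wild type, and the 2483 falls had -0.65 and -0.25. Each choice favours the comparison in which the probe sets were called. Changes in both backgrounds correlated across all probe sets with Pearson's r = 0.647 and Spearman's rho = 0.517. Probe set 253161_AT rose from 31.1 to 1546, a log2 change of 5.63 ± 0.33 (SE, n = 2 arrays per genotype; limma adjusted p = 0.000175), and 256569_AT rose from 18.0 to 842, a log2 change of 5.55 ± 0.14 (limma adjusted p = 2.03e-05). The falls were led by 258419_AT, at -6.05 ± 0.42 (limma adjusted p = 0.000298), and 255298_AT, at -5.45 ± 0.15 (limma adjusted p = 2.15e-05). As deposited, 253161_AT gave -4.33, 258419_AT gave 3.92 and the correlation was 0.403, and without bpc4 bpc6 replicate 2 the comparison had 2845 calls.

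The bpc4 bpc6 effect was measured in the same way within the lhp1-4 background. Against lhp1-4 the triple mutant had 496 rises and 257 falls, and among changes of at least 2-fold there were 218 rises and 46 falls. These were mostly other probe sets than those changed by bpc4 bpc6 in the presence of LHP1. Of the 219 rises of bpc4 bpc6 over wild type 26 rose and 11 fell here, where independent lists would share 4.78 rises, and their median log2 change went from 0.94 to 0.03. Of its 191 falls 13 fell and 23 rose, where 2.16 falls would be shared, and the median went from -0.82 to -0.01. Chosen the other way round, the 496 rises over lhp1-4 had a median log2 change of 0.91 there and -0.04 in bpc4 bpc6 against wild type. The 257 falls had -0.69 and -0.08. Each choice favours the comparison in which the probe sets were called, so part of these drops comes from the choice. Across all probe sets the changes in both backgrounds, which share no array, correlated with Pearson's r = 0.0467 and Spearman's rho = 0.0578. Probe set 253161_AT rose from 106 to 1546, a log2 change of 3.87 ± 0.33 (SE, n = 2 arrays per genotype; limma adjusted p = 0.00478), and 262373_AT rose from 13.4 to 191, a log2 change of 3.84 ± 0.15 (limma adjusted p = 0.00057). Probe set 260471_AT fell from 258 to 36.2, a log2 change of -2.83 ± 0.17 (limma adjusted p = 0.00177), and 252607_AT fell from 379 to 61.7, a log2 change of -2.62 ± 0.31 (limma adjusted p = 0.0107). The 753 calls dropped to 97 and 34 without lhp1-4 replicates 1 and 2 and to 196 and 219 without triple mutant replicates 1 and 2, with 386 when only these 2 genotypes were in the model, and 252607_AT lost its call without any of those 4 arrays, at adjusted p from 0.0558 to 0.0924, and on the values as deposited, where its change stayed at -2.62 but the adjusted p was 0.764. The call of 253161_AT ended without lhp1-4 replicate 2 (limma adjusted p = 0.0504), its direction rests on the restored scale, with -6.10 as deposited, and r turned to -0.0235 without bpc4 bpc6 replicate 1, was 0.107 without bpc4 bpc6 replicate 2 and 0.0037 without wild type replicate 2.

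**Figure D3:**
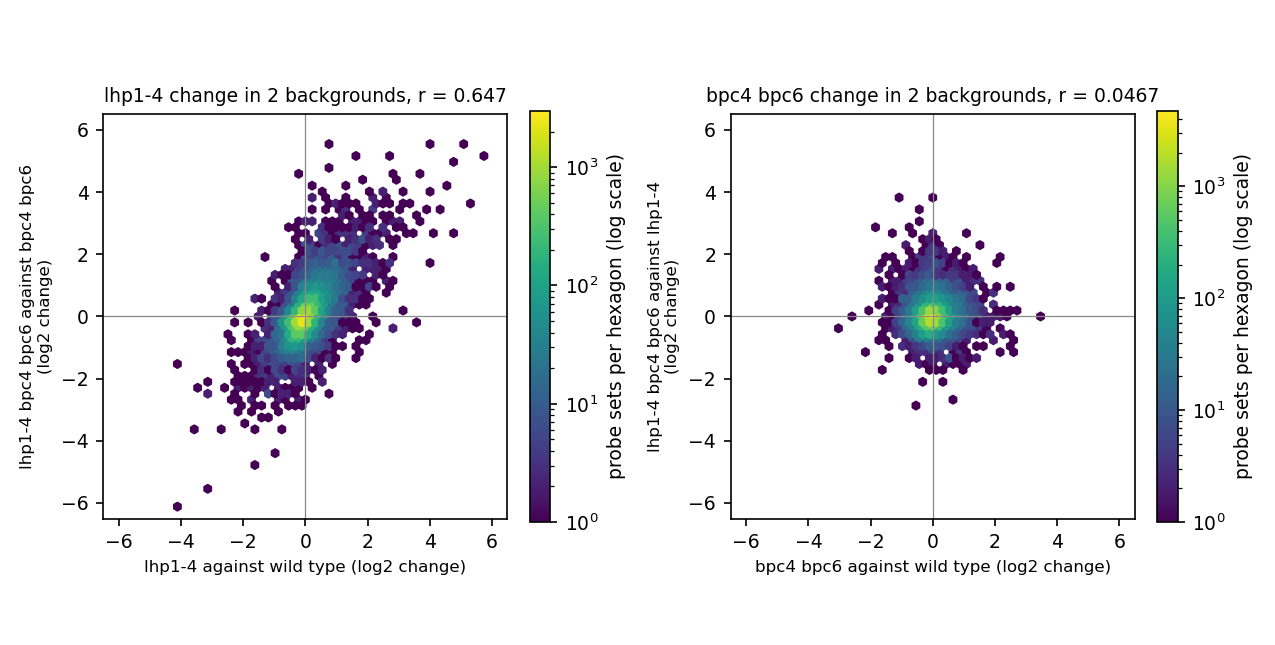
Log2 changes of 22716 probe sets (hexagons, coloured by number of probe sets on a log scale) for the lhp1-4 effect (left) and the bpc4 bpc6 effect (right), each without (horizontal axis) and with (vertical axis) the other lesion. The left cloud runs along the diagonal (r = 0.647), and the right cloud has r = 0.0467.

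The interaction tested whether the effects of both lesions added up on the log2 scale. They did not for 529 probe sets, 349 above and 180 below the sum of the separate changes. In 311 of these the triple mutant was the genotype farthest from the mean of the others, above it in 250, and in 154 it was bpc4 bpc6. The same counts over all probe sets were not taken. The triple mutant had the most changes against wild type, so it can be farthest without an interaction too. The triple mutant rose over both parents in 154 probe sets with a positive interaction in which neither lhp1-4 nor bpc4 bpc6 had a call against wild type, and fell below both in 33 with a negative interaction. Among the rises of bpc4 bpc6 over wild type 98 of 219 had an interaction call, 97 of them of the opposite sign, and among its falls 83 of 191 had a call, all 83 of the opposite sign. Among the changes of lhp1-4 an interaction was called in 110 of 802 rises, with 68 of the same sign and 42 of the opposite sign, and in 52 of 564 falls, with 19 and 33. The wild type and mutant values that make up the changes by which these probe sets were chosen both enter the interaction with the opposite sign, which by itself favours opposite signs. Without a given array the count was 23 and 106 (lhp1-4 replicates 2 and 1), 146 and 230 (triple mutant replicates 1 and 2), 148 and 312 (bpc4 bpc6 replicates 2 and 1) and 160 (wild type replicate 1).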

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

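Of the tests in this part, the one for wild type arrays standing apart was chosen after the result was seen.

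An effect of bpc4 bpc6 that differed with the lhp1-4 background was found by limma's interaction test in 529 probe sets. The count was 401 without wild type replicate 2 and 23 to 312 without each of the other 7 arrays, lowest without lhp1-4 replicate 2. The largest positive values were those of 253161_AT, 4.91 ± 0.46 on the log2 scale (SE, n = 2 arrays per genotype; limma adjusted p = 0.00821), and 267461_AT, 4.78 ± 0.51 (limma adjusted p = 0.0113). Both signs rest on the restored scale, since the values as deposited gave -5.06 and -5.19. Probe set 253161_AT stood at 64.0 in wild type, 106 in lhp1-4, 31.1 in bpc4 bpc6 and 1546 in the triple mutant, and 267461_AT at 164, 148, 43.1 and 1068. The largest negative values were those of 260522_X_AT, -3.45 ± 0.40 (limma adjusted p = 0.0135), and 245465_AT, -3.34 ± 0.39 (limma adjusted p = 0.0136). Probe set 260522_X_AT stood at 33.6, 17.4, 353 and 16.7 in the same order of genotypes, so that it was high in bpc4 bpc6 only when LHP1 was present. Probe set 245465_AT stood at 15.3 in wild type, 115 in lhp1-4, 90.3 in bpc4 bpc6 and 67.3 in the triple mutant. Leaving out 1 array ended the call of 253161_AT without lhp1-4 replicate 2 (limma adjusted p = 0.050, just above the threshold), of 260522_X_AT without triple mutant replicate 1 (0.054), of 267461_AT without lhp1-4 replicate 1 (0.0511), lhp1-4 replicate 2 (0.0669) or wild type replicate 1 (0.0539), and of 245465_AT without the same 3 arrays (0.0645, 0.0669 and 0.0521).

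Technical sources of the 529 calls were weighed as follows. Restoring the scale of values of 1000 or more cannot have made most of them, since 432 of the 529 lay in probe sets without scaled or open values. Of the probe sets in which no value was scaled 2.09% had a call, against 2.33% of all. The share was thus higher in probe sets with scaled values, and for those calls an effect of the restoration stays open. Quantile normalization left 472 calls, 436 of them among the 529. Per the submitters' notes the authors used RMA, which itself quantile-normalises arrays, so a second round cannot exclude an effect of scaling. It still moved the values, with the median interaction over all probe sets going from 0.021 to -0.0029. Centring each array on its median, which also moved the arrays, left 645 calls, 503 of them among the 529. Wild type arrays standing apart cannot be told apart from genotype here. Wild type was the odd genotype in 9.83% of the calls, with no share over all probe sets taken to set beside it. But if the lhp1-4 and bpc4 bpc6 changes add up, displaced wild type arrays can leave another genotype as the odd one. The covariance of both changes taken against different wild type arrays was 0.0217 to 0.0447 over 8 pairings. Its highest value lies too close to the 0.0456 or more within the bpc4 bpc6 comparison for 2 arrays per genotype to decide. What also stays open is a difference in growth or handling between the pools of the triple mutant or bpc4 bpc6 and the other pools, which cannot be told apart from genotype here, and an action of BPC4 and BPC6 through LHP1 as the cause remains an untested hypothesis.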

How the results depend on the processing

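Chosen only after the data were seen were the values as deposited, the probe sets without scaled or open values, the floors of 2.5 and 3.5 and the undecided probe sets read as dim. The total counts of calls and the 156 shared calls held within 1.5 times under the block, median centring, quantile normalization, trended and robust moderation, both floors, the undecided probe sets read as dim and the probe sets without scaled or open values. The correlations were not computed under the block and the moderation; under the others that of lhp1-4 with bpc4 bpc6 changes was 0.418 to 0.443, that of lhp1-4 changes between backgrounds 0.644 to 0.651 and that of bpc4 bpc6 changes between backgrounds 0.0466 to 0.0673. Counts in 1 direction moved more: median centring took the falls from 564 to 898 in lhp1-4 and from 191 to 322 in bpc4 bpc6, and trended and robust moderation took those of the triple mutant against lhp1-4 from 257 to 390. Gene list tests were not run, as probe sets were not paired with genes. The labels tie replicate numbers to no batch. Differences between replicates correlated at 0.101 to 0.231 for 4 of the 6 pairs of genotypes but at -0.00863 and -0.184 for the others, so the numbers were not taken as pairing; a batch shared by some genotypes is not excluded. The fit with replicate number as a block gave 1397, 470, 5544, 788 and 5006 calls for lhp1-4, bpc4 bpc6 and the triple mutant against wild type and for the triple mutant against lhp1-4 and bpc4 bpc6, 566 interactions and 173 shared calls. In the same order, a 2-fold minimum gave 523, 145, 1449, 264 and 1347, with 48 shared, and adjusted p under 0.01 gave 396, 28, 2623, 124 and 2389, with 60 interactions and 9 shared; both are stricter by construction. Array weights gave 161 calls for bpc4 bpc6 against wild type and 78 shared. With only the compared genotypes in the model there were 3369 calls for the triple mutant against wild type, 386 against lhp1-4, and for bpc4 bpc6 0 limma calls and 0 shared, with 3139 at unadjusted p under 0.05; such a model has fewer arrays. Leaving out the dim probe sets gave 638 calls for bpc4 bpc6. The cause of the shifts with array weights and dim probe sets was not tested.

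Leaving out 1 array leaves a genotype with a lone array, assumed to vary like the others. Calls then ranged from 289 to 1832 for lhp1-4, from 41 to 380 for bpc4 bpc6 and from 3822 to 5390 for the triple mutant against wild type, from 34 to 701 for the triple mutant against lhp1-4 and from 2845 to 5021 against bpc4 bpc6, with 23 to 401 interactions and 22 to 254 shared calls. Lowest were lhp1-4 without lhp1-4 replicate 1, bpc4 bpc6 without wild type replicate 1, and the interaction and the triple mutant against lhp1-4 without lhp1-4 replicate 2. The correlation of lhp1-4 with bpc4 bpc6 changes ranged from 0.373 to 0.561, that of lhp1-4 changes between backgrounds from 0.575 to 0.646, and that of bpc4 bpc6 changes between backgrounds from -0.0235 to 0.107. The values as deposited gave 0.403 for the lhp1-4 changes between backgrounds. Of 463 alternative values of the 24 named changes, 437 kept sign and call, 18 lost the call and 8 reversed. All 8 came from the values as deposited, where values of 1000 or more are stored divided by 1000: 258419_AT at 5.82 in lhp1-4 and 4.35 in the triple mutant against wild type and 3.92 against bpc4 bpc6, 246687_AT at -3.66 in the triple mutant against wild type, 253161_AT at -6.10 against lhp1-4, -4.33 against bpc4 bpc6 and -5.06 for the interaction, and 267461_AT at -5.19 for the interaction. The share of rises went from 58.7% to 44.7% in lhp1-4 and from 53.4% to 45.0% in bpc4 bpc6 under median centring. Signal over background was not measured, so dim probe sets limit the falls that could be seen.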

Other observations

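In this part the tests of noise between arrays, of wild type arrays standing apart, of dim probe sets and of array scaling were chosen after the results were seen.

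The lhp1-4 changes over all probe sets, chosen by no call, covaried more between arrays when BPC4 and BPC6 were lost. Covariances between independent pairs of single arrays, which noise does not inflate, were 0.138 and 0.139 for lhp1-4 against wild type and 0.282 to 0.298 for the triple mutant against bpc4 bpc6. The covariance between both lhp1-4 effects was 0.134 to 0.178 over 16 pairings of single arrays. For bpc4 bpc6 it was 0.0456 to 0.0621 against wild type and 0.0744 to 0.0803 within lhp1-4.

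The bpc4 bpc6 changes differed between backgrounds, with r = 0.0467, or -0.0235 and 0.107 without bpc4 bpc6 replicates 1 and 2. Noise between arrays would lower r but not the covariance, and the covariance between backgrounds reached 0.0192 at most over 16 pairings, below the 0.0456 or more within the wild type background. If the wild type arrays stood apart, lhp1-4 and bpc4 bpc6 changes taken against different wild type arrays would covary as much as separate arrays of the bpc4 bpc6 comparison. They covaried at 0.0217 to 0.0447 over 8 pairings, all below the 0.0456 and 0.0621 between separate arrays of the bpc4 bpc6 comparison. The gap from the highest is too small for 2 arrays per genotype, so this explanation and a true dependence on LHP1 cannot be told apart. Transcripts changed by both lesions would raise these covariances too. An untested hypothesis is that BPC4 and BPC6 act on part of their targets only when LHP1 is present.

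In lhp1-4, 69.0% of the changes of at least 2-fold were rises, and 61.1% to 69.8% when each array was left out in turn, lowest without wild type replicate 2. Restored values and scaling between arrays do not account for it: rises made up 67.8% among probe sets with no scaled value, 310 against 147 (exact 95% interval 63.3% to 72.1%, with probe sets taken as independent, which they are not), and 63.0% with each array centred on its median, 339 against 199 (58.8% to 67.1%). Dim probe sets, which can hardly fall, would produce the excess, and it was absent from settled probe sets above the median level in wild type, with 45.5% rises, 86 against 103 (38.3% to 52.9%), while those at or below it had 82.3%, 275 against 59. The wild type arrays are part of the comparison, which favours falls above that median. With the level taken from the bpc4 bpc6 arrays instead there were 105 rises against 86 falls above the median (47.6% to 62.2% rises) and 256 against 76 at or below it. With the level taken over all 8 arrays the excess was present on both sides. There were 142 rises against 71 falls above the median (59.9% to 73.0% rises) and 219 against 91 at or below it. That level includes the lhp1-4 and triple mutant arrays, which favours rises above the median. The limits of dim probe sets thus stay open as the source, and release of Polycomb-silenced transcripts in lhp1-4, which would also be dim in wild type, remains an untested hypothesis.

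Of the 30 probe sets left out as undecided, 14 had values of 4.38 to 9.78 in all wild type and bpc4 bpc6 arrays and of 28.6 to 707 in all lhp1-4 and triple mutant arrays. Read as dim signals they would be higher with lhp1-4 by a median of 16.6-fold, and read as divided by 1000 they would be lower by a median of 60.2-fold.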
